A study of Homo sapiens with 3 samples.

How the data were processed

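The series holds RNA sequencing of T47D, an estrogen receptor-positive human breast cancer cell line. The samples are 1 control library and 2 libraries of cells carrying a short hairpin RNA (shRNA) against ERINA, a long noncoding RNA. Per the labels, the hairpins were delivered by lentivirus and stable cells were selected with puromycin. The genotype label put the 2 hairpin libraries, named shRNA1 and shRNA2, in a single knockdown group. The control is described as a control hairpin in its description label, whereas its shRNA label reads None. The 2 hairpin libraries come from cells selected with different hairpins, and no condition has a repeat library. The p-values therefore measure only the spread between these 2 libraries, which holds any difference between the hairpins besides technical spread. The hairpin sequences are not given in the sources used here, and neither are the library kit, the read length and whether reads were counted by strand. The labels' extraction protocol covers RNA isolation and quantitative PCR.

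The deposited values are FPKM, fragments scaled to transcript length and to the number of mapped fragments, with 1 column per library, per the file headers. The authors also deposited a lower and an upper confidence bound of each FPKM and a quantification status of OK, HIDATA or FAIL, per the file headers. STAR, RSEM and genome build GRCh38 are named in the submitters' processing notes, with no version and no role. The column layout resembles that of a Cufflinks or Cuffdiff table, which those notes do not name, so the software behind the FPKM and its bounds was not settled here. The annotation release, filters and any scaling between libraries are not given in the sources used here. Gene identifiers were matched to GENCODE release 29 on GRCh38, which held 57435 of the 58039 listed genes (99.0%), and 97.5% of the matched genes lay inside the deposited locus. Types, coordinates, transcript lengths and sequences came from that release, which may not be the authors' own. No gene is listed under the name ERINA. RefSeq gives ERINA as a synonym of LINC00992, and the values listed for that gene were used. The plan had allowed only a gene named ERINA in the deposited table or in the gene name table, so this match goes beyond the plan.

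The values are not counts, so no count model was used. The total FPKM was 790290 in the control, 860240 with shRNA1 and 808451 with shRNA2. From the FPKM that a single fragment gives in genes with 1 annotated transcript, the depth was estimated at 32300000, 33100000 and 33300000 fragments. The median log2 change of tested genes was -0.0006 with shRNA1 and 0 with shRNA2 before any scaling here. The deposited values may thus have been scaled between libraries already, and the depths would then be scaled sizes. Single fragments were recognised by deposited bounds whose implied standard deviation about equals the FPKM. At such a depth, 1 fragment is worth about 0.3 FPKM over 100 nt before any correction for effective length. That correction is not known here and would raise the value for short transcripts. By its bounds RNU6-2, listed at 51.0 FPKM in the control with an upper bound of 153, held a single fragment. RMRP and RPPH1, the RNA components of RNase MRP and RNase P, together took 18.0%, 18.1% and 16.9% of the total. In each library 13 genes had the status HIDATA, and 4 of the tested genes had a status other than OK in a library. No gene had the same nonzero FPKM in any pair of libraries (0 in each of the 3 pairs), so no library was a copy of another.

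Changes were computed on log2(FPKM + 0.5) for the 13112 genes with a mean FPKM of at least 1 over the 3 libraries, 11546 of them protein-coding. This scale understates the fold change of low genes. A fold printed as a ratio of FPKM has no pseudocount. The test was limma (lmFit, then eBayes with a mean-variance trend; version 3.58.1 in R 4.3.3) for knockdown against control, with Benjamini-Hochberg adjustment and a threshold of 0.05. It has 1 residual degree of freedom, from the difference between the shRNA libraries. The control library has no replicate check and is assumed to vary like them. Genes at least 2-fold apart between single libraries were counted with no test. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

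Gene lists with at least 5 measured members were tested with limma's camera at its preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Each list median was also placed among 10000 random lists of the same size matched on mean expression, separately for each shRNA. The lists were E2F targets and DNA replication, mitosis, RB and E2F pathway components, estrogen-induced genes, luminal identity, basal and myoepithelial markers, mesenchymal and stromal markers, immune and endothelial markers, p53 targets, apoptosis regulators, interferon-stimulated genes, NF-kB and inflammatory genes, unfolded protein and integrated stress response, immediate early genes, cholesterol synthesis, fatty acid synthesis and lipid storage, hypoxia and glycolysis, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, cytosolic ribosomal proteins, MYC targets and ribosome biogenesis, replication-dependent histones, TGF-beta and YAP targets, and housekeeping genes. A list of motile cilia genes was written after the values had been seen.

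Named genes were ERINA, the 12 higher and 12 lower genes with the largest change under the weaker shRNA, 16 fixed key genes, up to 4 members of each list with the largest mean change, and the 5 genes furthest apart between the shRNAs in each direction. After seeing that small RNA genes filled the first of these groups, the same rule of size was also applied to protein-coding genes alone. Some genes that these rules name are not reported here. Other genes that are named are said to have been chosen after their values were seen. The groups, the tests, the lists, the naming rule and the alternatives of pseudocount, filter, scaling, eBayes option, list test, fold threshold and left-out library were fixed before the data were examined. Added later were fits of protein-coding genes only, of genes above 0 in all libraries, of genes with status OK, and with the trend on GC content and transcript length removed.

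Tests were run on simulated data for knockdown against control, with 200 changed genes in each of 20 simulations. With noise resampled from the data over all 13112 genes, limma recovered 4.3% of 2-fold and 57.9% of 4-fold changes, with 37.2 false calls on average. The other variants were added after a first run of this kind had given many false calls. With noise from limma's own model over all genes, 18.8% and 71.1% were recovered, with 7.9 false calls. Over the 11546 protein-coding genes, resampled noise gave 50.1%, 94.4% and 2.6 false calls, and model noise gave 86.3%, 99.7% and 34.7. On 20 simulated lists of 50 genes lowered by a log2 change of -0.6, camera recovered 20 and called 0 of 380 unchanged lists. The simulated genes varied independently, so this gives no rate of false calls for lists whose members vary together. For 3' UTR sequences, a planted 7-base word was recovered in 20 of 20 simulations over 11444 genes. Words of 7 bases found in the longest 3' UTR of at least 100 genes were scored by z, the mean change of genes holding the word over its standard error, after the dependence on 3' UTR length, GC content and expression was removed. Because both shRNAs share the control, 100 sets of unchanged libraries with the spread seen between the shRNA libraries were simulated.

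Small RNA genes with near-identical copies, histones, ribosomal proteins and overlapping or antisense genes are uncertain, since the way reads were divided between them is not given in the sources used here. A gene listed at 0 may be a failed estimate, so such genes are given by library, with no fold.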

Results

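RNA was sequenced from T47D, an estrogen receptor-positive breast cancer cell line, in 1 control library and 2 libraries with stable knockdown of the long noncoding RNA ERINA, each made with a different shRNA. The deposited FPKM covered 58039 genes, of which 13112 reached a mean FPKM of at least 1 and were tested. The depth estimated from single-fragment genes was 32300000 fragments in the control, 33100000 with shRNA1 and 33300000 with shRNA2. Any scaling of the deposited values between libraries would alter these figures. Across protein-coding genes, which are not independent replicates, log2 values correlated at r = 0.994 between the shRNA libraries, at 0.971 between control and shRNA1 and at 0.980 between control and shRNA2.

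ERINA, listed as LINC00992 (ENSG00000248663), was far lower with both shRNAs. It is a long intergenic noncoding RNA at 117415509 to 117546298 on chromosome 5 of GRCh38. Its level was 63.4 FPKM in the control (deposited interval 38.4 to 88.5), 5.21 FPKM with shRNA1 (2.09 to 8.34) and 8.91 FPKM with shRNA2 (4.04 to 13.8). The control was 12.2-fold above shRNA1 and 7.12-fold above shRNA2, and both knockdown intervals lay below the control interval. In limma over all tested genes the log2 change was -3.12 (SE 0.33), with a Benjamini-Hochberg adjusted p of 0.0816, which did not pass, and 0.0118 to 0.109 over the alternatives.

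The comparison of knockdown with control asks which transcripts differ when ERINA is reduced. GINS2, a subunit of the replicative helicase complex, fell from 41.5 FPKM to 6.82 ± 0.901 (SD, n = 2), 6.08-fold lower; it overlaps GSE1 on the other strand. MYBL2, a transcription factor of cycling cells, fell from 43.3 to 7.27 ± 1.05 FPKM. In the other direction FOXJ1, the transcription factor of motile ciliogenesis, rose from 1.91 to 13.01 ± 0.6 FPKM, and CDC20B, a gene of multiciliated cells, from 1.13 to 9.90 ± 1.18 FPKM. All 4 moved the same way with both shRNAs, with limma adjusted p (Benjamini-Hochberg) of 0.0361 for GINS2, 0.0362 for MYBL2 and CDC20B, and 0.0222 for FOXJ1. Without the eBayes trend GINS2, MYBL2 and CDC20B no longer passed, and neither did PROSER1, given below. The 3' UTR of GINS2 holds 3 copies of the word TGGTGCA and that of MYBL2 holds 1, a word taken up among the additional observations. Of other named genes that were lower, PDXDC1, MYO1D, MKI67, ANLN, STC2, COL6A2, TNFRSF10B, APAF1, HMGCS1, ELOVL6 and NDRG1 hold it too, as does ESR1, and of those that were higher GREB1, ELOVL2, CMBL, NDUFA4 and POLR1A.

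**Figure D1:**
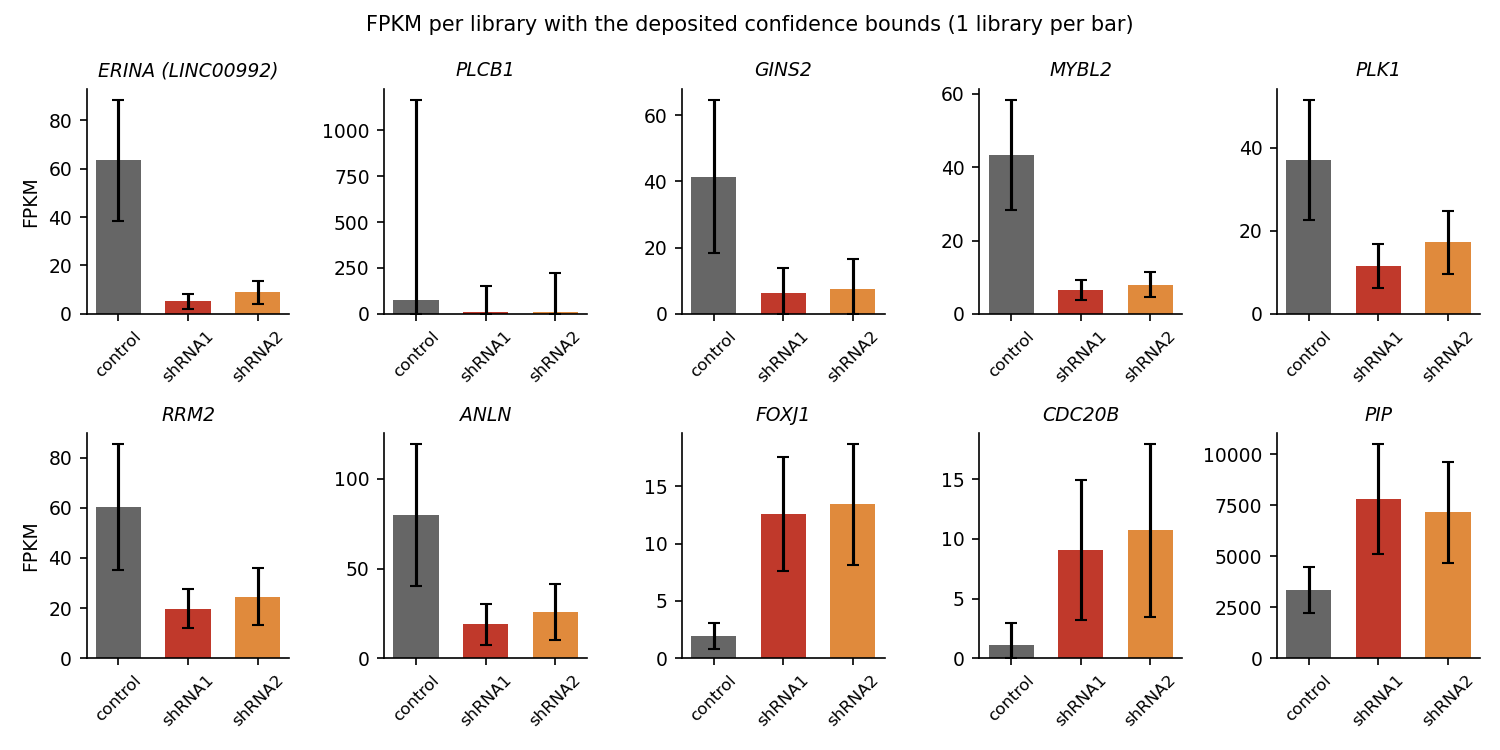
FPKM of 10 named genes on linear axes from 0, each panel with its own scale and 1 bar per library (control, shRNA1 and shRNA2), with error bars for the deposited confidence bounds. ERINA lies at 63.4 FPKM in the control and at 5.21 and 8.91 FPKM with the shRNAs, and the control bounds of PLCB1 reach from 0 to 1165 FPKM.

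In all, 11 genes rose and 35 fell in knockdown by limma at a Benjamini-Hochberg adjusted p under 0.05, and 3889 had an unadjusted p under 0.05. Of the 35 that fell, 26 were listed at 0 in both knockdown libraries and 9 were protein-coding. Of the 11 that rose, 6 were listed at 0 in the control and 3 were protein-coding. Besides GINS2 and MYBL2, the protein-coding genes that fell included PLCB1, a phosphoinositide phospholipase, from 73.0 to 10.5 and 10.2 FPKM. The deposited control interval of PLCB1 reaches from 0 to 1165 FPKM. CTD-2116N17.1, which overlaps KIAA0101 and CSNK1G1, fell from 26.8 to 4.78 and 5.002 FPKM. Also among them, and chosen after their values were seen, were S100A8, a calcium-binding protein (35.2 to 11.5 and 11.4 FPKM), and PDXDC1 (81.7 to 32.0 and 32.8 FPKM). The third protein-coding gene that rose was PROSER1, at 1.96, 16.1 and 14.2 FPKM in control, shRNA1 and shRNA2. SCARNA11 (6.54, 20.3 and 20.4 FPKM) and AL135791.1 (0, 2.997 and 2.88 FPKM) also rose and were chosen after their values were seen, to complete the count. In 100 simulations of unchanged libraries with the same test, a mean of 3.12 genes (at most 16) were called higher and 11.7 (at most 27) lower. With noise resampled from the data and 200 changed genes, limma made a mean of 37.2 false calls (16 to 55) over all genes. These came on top of true calls, with 4.3% of 2-fold and 57.9% of 4-fold changes recovered. The range therefore does not tell how many of the 46 calls made here are false. Scaling the libraries to the same total, which shifts the median of all genes by -0.12 with shRNA1 and -0.03 with shRNA2 on the log2 scale, gave 65 higher and 111 lower calls in place of 11 and 35. With protein-coding genes tested alone, an alternative chosen after seeing the data, limma called 821 genes higher and 1299 lower, against 0 in the simulations, where a mean of 444 genes had an unadjusted p under 0.05. In the simulations with 200 changed genes, false calls among protein-coding genes averaged 2.6 (0 to 6) with resampled noise and 34.7 (5 to 130) with noise from limma's model. All these simulations let the control vary only as the shRNA libraries do, so calls beyond them may reflect a state of the control library.

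By size of change, small RNA genes stood at the top in both directions. The 12 lower genes were VTRNA1-3, a vault RNA, SNORD116-14 and SNORD116-21, small nucleolar RNAs of the Prader-Willi locus, RNY3P13 and a Y_RNA copy, the small nucleolar RNAs SNORD46 and SNORD9, and the U6 copies RNU6-48P, RNU6-15P, RNU6-16P, RNU6-2 and RNU6-880P. All were listed at 0 in both knockdown libraries and passed limma at a Benjamini-Hochberg adjusted p of 0.00383. Their control levels ran from 51.0 FPKM, shared by the last 4 U6 copies, to 373 FPKM for VTRNA1-3. With both knockdown values at 0 there is no spread between them, so the pass follows from the zeros, and the deposited control intervals of all 12 start at 0. Of 294 genes under 300 nt with status OK, 0 had deposited intervals of both shRNAs clear of the control. Among the 12 higher genes, SNORD116-8 was at 0, 355 and 174 FPKM in control, shRNA1 and shRNA2, SNORD116-24 at 0, 169 and 249, RNU6-36P at 0, 72.9 and 105, RNU1-120P at 0, 6.44 and 5.44, and the pseudogene AC016700.6 at 0, 4.45 and 5.64. These 5 passed, and so did SNHG25, a small nucleolar RNA host gene, which rose from 3.05 to 92.7 ± 12.7 FPKM (SD, n = 2), with a limma adjusted p of 0.00657 (Benjamini-Hochberg). SNHG25 overlaps the gene SNORA50C, and its deposited intervals start at 0 in each library and reach 6.40, 345 and 323 FPKM in control, shRNA1 and shRNA2. The other 6 did not pass, namely SNORD116-15, SNORD89, SNORA10, TMSB4XP1, SNORA18 and SNORA17, all at 0 in the control, with limma adjusted p (Benjamini-Hochberg) of 0.0790 to 0.0877. SNORD116-8 no longer passed without the eBayes trend or with its robust option, and AC016700.6 not without the trend or with a pseudocount of 1. Small RNAs of this kind have many near-identical copies, and 31 of the 294 tested genes under 300 nt were at 0 in 1 shRNA library and at 10 FPKM or more in the other.

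Among protein-coding genes ranked by the same rule, the levels given here are in control, shRNA1 and shRNA2, and no gene named passed limma over all genes (Benjamini-Hochberg adjusted p of 0.0635 to 0.0902). Lower were SAA2, an acute phase apolipoprotein (6.68, 1.05 and 1.39 FPKM), POMK, a kinase of dystroglycan glycosylation (17.6, 3.31 and 4.63), NGFR, the low-affinity neurotrophin receptor (4.77, 0.613 and 1.08) and MYO1D, an unconventional myosin (48.6, 10.97 and 14.46). ENSG00000259522 (4.96, 0 and 0.109) and AC006538.4 (5.08, 0.777 and 0.790) overlap other genes. Higher were CRISP3, a secreted cysteine-rich protein (9.44, 37.0 and 28.9 FPKM), CYP4V2, a fatty acid hydroxylase (2.38, 9.03 and 8.20), ITPR1, an intracellular calcium channel (2.47, 13.1 and 8.27), and SLITRK6, a transmembrane protein of neuronal cells (0.545, 3.26 and 2.95). The others were DEFB126, a sperm-coating defensin (0.120, 3.62 and 1.72), ROPN1L, a sperm flagellum protein (0.419, 2.90 and 2.44), the acyl-CoA thioesterase ACOT6 (0.844, 5.54 and 3.61), MSMB, a secreted prostate protein (0.852, 4.29 and 3.49), and ODAM (0.700, 2.97 and 3.14). With protein-coding genes tested alone these all passed.

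Genes of the cell cycle were lower with both shRNAs. Of 58 measured E2F targets and DNA replication genes, 56 were lower with both, with a median log2 change of -0.62, and 3 fell over all genes, GINS2 and MYBL2 among them, against 45 adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, was at 60.3 FPKM in the control and at 19.7 and 24.5 FPKM with shRNA1 and shRNA2. All 44 measured mitosis genes were lower with both shRNAs (median -0.77), none passed over all genes in limma and 41 passed adjusted over the list alone. Among them ANLN, an actin-binding protein of the cleavage furrow, was at 79.9, 18.9 and 25.7 FPKM, KIF20A, a kinesin of cytokinesis, at 41.3, 13.2 and 17.8, and the mitotic kinases PLK1 at 37.1, 11.6 and 17.2 and AURKB at 34.4, 13.8 and 16.8. All 42 measured replication-dependent histone genes were also lower with both (median -0.70), none passed over all genes and 40 did adjusted over the list alone. HIST1H3D was at 39.8, 14.8 and 9.58 FPKM, HIST1H3J at 120, 61.0 and 58.2, HIST1H2AL at 214, 112 and 108, and HIST1H2BO at 374, 191 and 195, with division of reads between near-identical copies uncertain. Camera placed the lists below other genes at Benjamini-Hochberg adjusted p of 7.84e-18 for E2F targets, 3.64e-16 for mitosis and 9.09e-20 for histones. For each of the 3, camera gave a Benjamini-Hochberg adjusted p = 0.664 with an estimated correlation. Camera then works with the 1 residual degree of freedom, where hardly any list could pass, so this value decides nothing here or below. The RB and E2F list, with an estimated correlation of -0.006, still went from an unadjusted camera p of 0.000498 to 0.157. The estimates were far above the preset 0.01 for E2F targets (0.292), histones (0.508) and mitosis (0.909). Of lists given below, it was 0.836 for ribosomal proteins and 0.004 for immediate early genes. The small camera p-values at the preset thus take little account of members that moved together between the shRNA libraries. The value of 0.664 was the highest over the alternatives for each of the 15 lists past camera. The lowest (limma's camera, Benjamini-Hochberg) ran from 2.05e-25 for histones to 0.0137 for MYC targets. With each shRNA the 3 medians lay at the 0th percentile of matched random lists. With protein-coding genes tested alone by limma, 42 E2F targets, 38 mitosis genes and 38 histone genes passed, all lower.

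RB and E2F pathway components were mixed but lower on balance. Of 31 measured, 22 were lower and 7 higher with both shRNAs (median -0.39), none passed limma over all genes, and 9 lower and 1 higher passed adjusted over the list alone. Camera gave a Benjamini-Hochberg adjusted p of 0.00164, and adjusted p = 0.664 with an estimated correlation. The cell cycle inhibitors CDKN1C (2.32, 0.299 and 0.739 FPKM in control, shRNA1 and shRNA2) and CDKN2D (12.1, 3.90 and 4.61) and the cyclin CCNE2 (30.1, 12.9 and 15.9) were lower, whereas the transcription factor E2F5 was higher (18.2, 37.9 and 30.8). Of the fixed key genes, E2F1 was at 20.7, 14.6 and 15.2 FPKM, the cyclin CCNE1 at 5.90, 3.38 and 3.62, the tumour suppressor RB1 at 15.3, 12.1 and 13.04, the cyclin CCND1 at 57.7, 51.5 and 51.5, and the inhibitor CDKN1A at 57.4, 45.2 and 47.5. MKI67, the gene of the Ki-67 proliferation antigen, was at 5.57, 2.71 and 3.24 FPKM and MYC at 18.5, 17.9 and 17.4. None of the 15 key genes tested passed limma over all genes (Benjamini-Hochberg adjusted p of 0.0841 to 0.839). Limma on protein-coding genes alone passed 10 lower and 1 higher in this list.

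**Figure D2:**
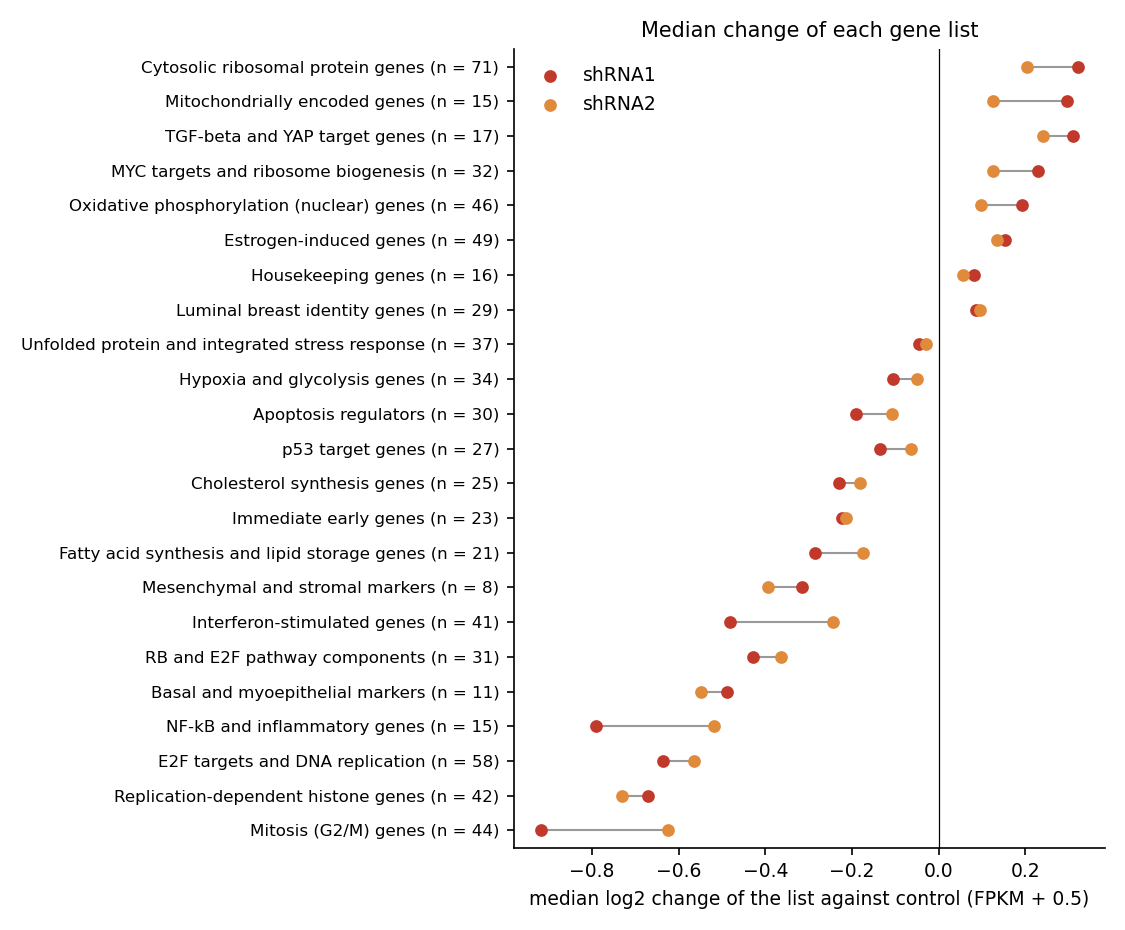
Median log2 change, on the log2(FPKM + 0.5) scale, of each of the 23 tested gene lists with shRNA1 and with shRNA2 against the single control library. The mitosis list lies at -0.92 and -0.63 and the cytosolic ribosomal protein list at 0.32 and 0.20.

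Estrogen-induced genes went both ways, slightly higher on balance. Of 49 measured, 29 were higher and 14 lower with both shRNAs (median 0.13, and 0.06 with the libraries scaled to the same total and 0.21 at a mean FPKM of at least 5), none passed limma over all genes, and 14 higher and 5 lower passed adjusted over the list alone. ANXA9, an annexin, was at 41.3, 93.9 and 76.3 FPKM in control, shRNA1 and shRNA2 and ELOVL2, a fatty acid elongase, at 0.599, 1.86 and 1.52, against 170, 72.2 and 86.6 for AREG, an EGF receptor ligand, and 93.1, 45.7 and 47.8 for STC2, a secreted glycoprotein hormone. Camera gave the list a Benjamini-Hochberg adjusted p of 0.0207, and adjusted p = 0.664 with an estimated correlation. The call was lost with no filter on low genes. The estrogen receptor gene ESR1 was at 16.8, 16.5 and 17.96 FPKM, a log2 change of 0.04 that became -0.039 with the same total. The progesterone receptor gene PGR was at 41.4, 55.4 and 53.7 FPKM, GREB1 at 39.1, 47.6 and 42.9 and the trefoil factor TFF1 at 6.39, 3.13 and 3.72. The apoptosis inhibitor BCL2 lay below the filter at 0.134, 0.121 and 0.150 FPKM. In limma on protein-coding genes alone, 15 estrogen-induced genes passed higher and 5 lower.

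Luminal identity genes as a list did not pass camera (29 measured, median 0.06, Benjamini-Hochberg adjusted p of 0.134; 0.664 with an estimated correlation). Its median was -0.02 with the same total and 0.09 at a mean FPKM of at least 5 or with the GC and length trend removed, with 0.09 for shRNA1 and 0.10 for shRNA2 alone. With the GC and length trend removed the list did pass camera (Benjamini-Hochberg adjusted p of 0.0468). None of its members passed over all genes and 4 passed higher adjusted over the list alone. PIP, a secreted protein of apocrine cells, was at 3346, 7810 and 7166 FPKM, the keratin KRT19 at 3152, 5210 and 4281, and MLPH at 29.01, 49.8 and 36.2. The pioneer factor FOXA1 was at 65.7, 94.8 and 91.5 FPKM and GATA3 at 43.4, 39.0 and 40.0. Basal and myoepithelial markers were lower, 8 of 11 measured with both shRNAs (median -0.57), none over all genes and 4 adjusted over the list alone, with a camera Benjamini-Hochberg adjusted p of 0.0129 and adjusted p = 0.664 with an estimated correlation. With a mean FPKM of at least 5 this call was lost, over 5 members with a median of -0.20, and with no filter the median was -0.16 over 22. The integrin ITGA6 was at 10.8, 4.55 and 5.58 FPKM, TRIM29 at 5.45, 2.49 and 2.67, the laminin LAMB3 at 3.70, 1.72 and 2.07 and the hyaluronan receptor CD44 at 14.5, 7.97 and 9.65. Of 8 measured mesenchymal and stromal markers 4 were lower with both (median -0.32, and -0.04 over 23 with no filter), and the list did not pass camera (Benjamini-Hochberg adjusted p of 0.208), with 0 members over all genes and 2 lower adjusted over the list alone. The collagen COL1A1 was at 5.16, 1.65 and 2.10 FPKM, COL6A1 at 5.10, 1.57 and 2.40, COL6A2 at 1.86, 0.832 and 1.11, and vimentin (VIM) at 1.47, 2.06 and 2.70. Of the immune and endothelial markers 1 was measured, too few for a test. With no filter, the only alternative that gave this list a test, 15 members had a median of -0.03 and did not pass camera (Benjamini-Hochberg adjusted p of 0.107). With protein-coding genes tested alone by limma, 6 luminal genes passed higher, and 4 basal and 2 mesenchymal markers lower.

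Inflammatory and interferon-stimulated genes were lower on balance. Of 15 measured NF-kB and inflammatory genes 13 were lower with both shRNAs (median -0.57, camera Benjamini-Hochberg adjusted p of 7.69e-05, adjusted p = 0.664 with an estimated correlation), none over all genes and 10 adjusted over the list alone. BIRC3, an inhibitor of apoptosis, was at 7.82, 2.31 and 3.23 FPKM in control, shRNA1 and shRNA2, the subunit NFKB2 at 26.8, 11.6 and 12.7, the dendritic cell marker CD83 at 4.50, 1.43 and 2.10 and the cytokine TNF at 3.19, 1.04 and 1.56. Of 41 interferon-stimulated genes 27 were lower with both (median -0.38, at -0.48 with shRNA1 and -0.24 with shRNA2, camera Benjamini-Hochberg adjusted p of 0.000929, adjusted p = 0.664 with an estimated correlation), with 0 past limma over all genes and 0 adjusted over the list alone. The antiviral genes OAS1 (12.004, 4.22 and 6.32 FPKM), MX1 (51.4, 19.97 and 31.8), IFI27 (19.6, 5.99 and 10.95) and IFIT1 (19.8, 8.45 and 15.5) were lower, and MX2 was higher (0.685, 2.72 and 1.82). Of 23 immediate early genes 17 were lower (median -0.24, and -0.14 at a mean FPKM of at least 5, camera Benjamini-Hochberg adjusted p of 0.00571, adjusted p = 0.664 with an estimated correlation), with 0 over all genes and 0 adjusted over the list alone. The MAP kinase phosphatases DUSP6 (2.86, 0.581 and 1.16 FPKM) and DUSP4 (3.85, 1.47 and 2.22), JUN (17.5, 10.3 and 10.5) and IER3 (86.9, 57.1 and 64.1) had the largest changes in this list. In limma on protein-coding genes alone, 9 NF-kB and inflammatory genes passed lower, 16 interferon-stimulated genes lower and 1 higher, and 4 immediate early genes lower.

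Apoptosis regulators were also lower, 19 of 30 with both shRNAs (median -0.13, and -0.21 with the same total, camera Benjamini-Hochberg adjusted p of 0.0246, adjusted p = 0.664 with an estimated correlation), with 0 over all genes and 3 adjusted over the list alone. The call was lost with a mean FPKM of at least 5. The death receptor TNFRSF10B was at 25.5, 14.98 and 16.7 FPKM in control, shRNA1 and shRNA2, the pore-forming protein BAK1 at 15.9, 7.95 and 8.96 and APAF1, the apoptosome scaffold, at 5.58, 3.18 and 3.77. The p53 targets did not pass camera (27 measured, median -0.15, at -0.06 with shRNA2 alone or a mean FPKM of at least 5 and -0.23 with the same total, Benjamini-Hochberg adjusted p of 0.234; 0.6698 with an estimated correlation), with 0 over all genes and 1 higher adjusted over the list alone. The stress cytokine GDF15 was at 9.15, 2.57 and 4.70 FPKM, the DNA repair gene DDB2 at 66.1, 41.8 and 46.7 and CMBL at 16.8, 35.5 and 34.9. Nor did the unfolded protein and integrated stress response pass (37 measured, median -0.01, at -0.09 with the same total and 0.01 with the GC and length trend removed, camera Benjamini-Hochberg adjusted p of 0.413), with 0 over all genes and 0 adjusted over the list alone. In it the mitochondrial folate enzyme MTHFD2 was at 167, 64.5 and 83.0 FPKM, the pseudokinase TRIB3 at 42.1, 28.2 and 31.1, DDIT4 at 73.7, 110 and 105, ATF5 at 2.12, 4.24 and 2.61 and DDIT3 at 45.7, 35.8 and 37.99. In limma on protein-coding genes alone, 7 apoptosis regulators passed lower, 5 p53 targets lower and 2 higher, and 2 stress response genes lower and 1 higher.

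Cytosolic ribosomal protein genes were higher, 65 of 71 measured with both shRNAs (median 0.27, camera Benjamini-Hochberg adjusted p of 8.06e-10, adjusted p = 0.664 with an estimated correlation), with 0 over all genes and 0 adjusted over the list alone. Its median lay at the 100th percentile of matched random lists with each shRNA, which share the control and leave out correlation between members. RPL10A was at 1211, 1780 and 1599 FPKM in control, shRNA1 and shRNA2, RPS18 at 2826, 3924 and 3573, RPL36 at 799, 1159 and 984 and RPS12 at 737, 1016 and 934. MYC targets and ribosome biogenesis genes were higher in 20 of 32 (median 0.19, at 0.11 with the same total and 0.12 with shRNA2 alone, camera Benjamini-Hochberg adjusted p of 0.0246, adjusted p = 0.664 with an estimated correlation), with 0 over all genes and 0 adjusted over the list alone. RRS1 was at 13.2, 22.8 and 18.5 FPKM and the polymerase subunit POLR1A at 3.88, 5.46 and 5.27, with BOP1 at 23.5, 16.2 and 16.9 and ODC1, the ornithine decarboxylase, at 31.0, 20.4 and 25.04. TGF-beta and YAP targets were higher in 13 of 17 (median 0.22, and 0.41 at a mean FPKM of at least 5, camera Benjamini-Hochberg adjusted p of 0.00742, adjusted p = 0.664 with an estimated correlation), with 0 over all genes and 6 adjusted over the list alone. ID2 was at 13.2, 21.6 and 20.1 FPKM, SMAD7 at 2.90, 4.61 and 4.75, AJUBA at 15.1, 21.5 and 21.1 and TGFBI at 1.55, 0.847 and 0.865. With no filter the TGF-beta call was lost. Housekeeping genes did not pass (16 measured, median 0.08, and 0.004 with the same total, camera Benjamini-Hochberg adjusted p of 0.315), with 0 over all genes and 1 higher adjusted over the list alone. The transferrin receptor TFRC was at 325, 560 and 515 FPKM, HPRT1 at 9.15, 13.3 and 12.8 and EEF1A1 at 1856, 2593 and 2496. With protein-coding genes tested alone by limma, 3 ribosomal protein genes passed higher, 1 MYC target higher and 1 lower, 6 TGF-beta and YAP targets higher, and 3 housekeeping genes higher and 1 lower.

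Cholesterol synthesis genes were lower, 19 of 25 with both shRNAs (median -0.21, camera Benjamini-Hochberg adjusted p of 0.00680, adjusted p = 0.664 with an estimated correlation), with 0 over all genes and 5 lower and 1 higher adjusted over the list alone. The synthase HMGCS1 was at 39.1, 14.9 and 19.3 FPKM in control, shRNA1 and shRNA2, the sterol sensor partner INSIG1 at 22.9, 9.59 and 10.6, STARD4 at 11.1, 4.52 and 6.00 and ACAT2 at 27.8, 15.9 and 19.7. Fatty acid synthesis and lipid storage genes did not pass (21 measured, median -0.28, and -0.17 with shRNA2 alone, camera Benjamini-Hochberg adjusted p of 0.134), with 0 over all genes and 3 lower and 2 higher adjusted over the list alone. The desaturase SCD was at 175, 94.1 and 116.01 FPKM, the elongases ELOVL6 at 11.02, 3.93 and 6.69 and ELOVL5 at 133, 209 and 189, and the fatty acid transporter CD36 at 20.1, 30.1 and 31.3. Hypoxia and glycolysis genes did not pass (34 measured, median -0.11, at -0.05 with shRNA2 alone and -0.19 with the same total, camera Benjamini-Hochberg adjusted p of 0.359), with 0 over all genes and 0 adjusted over the list alone. ANGPTL4 was at 18.01, 7.99 and 9.50 FPKM, NDRG1 at 37.6, 16.6 and 25.7, P4HA2 at 37.0, 20.1 and 24.4 and ANKRD37 at 1.81, 4.30 and 3.64. Nuclear genes of oxidative phosphorylation were higher in 31 of 46 (median 0.15, at 0.08 with the same total and 0.10 with the GC and length trend removed or with shRNA2 alone, camera Benjamini-Hochberg adjusted p of 0.0241, adjusted p = 0.664 with an estimated correlation), with 0 over all genes and 0 adjusted over the list alone. The call was lost with the same total and with the GC and length trend removed. NDUFA4 was at 118, 179 and 152 FPKM, NDUFA1 at 51.1, 69.2 and 65.5, NDUFB3 at 72.4, 101 and 86.1 and SDHA at 108, 75.8 and 83.5. Mitochondrially encoded genes did not pass (15 measured, median 0.24, at 0.30 with shRNA1 and 0.13 with shRNA2, -0.004 over the 13 protein-coding members, 0.12 at a mean FPKM of at least 5 and 0.14 with the GC and length trend removed, camera Benjamini-Hochberg adjusted p of 0.188), with 0 over all genes and 0 adjusted over the list alone. MT-CO2 was at 326, 436 and 408 FPKM, the ribosomal RNAs MT-RNR2 at 135, 206 and 170 and MT-RNR1 at 35.1, 48.7 and 43.1, and MT-ATP8 at 9.33, 12.8 and 15.3. When limma tested protein-coding genes alone, 7 cholesterol genes passed lower and 1 higher, 5 fatty acid genes lower and 2 higher, 6 hypoxia genes lower and 2 higher, 1 nuclear oxidative phosphorylation gene lower and 2 higher, and 2 mitochondrially encoded genes higher.

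Changes with the shRNAs went largely the same way relative to the shared control. At least 2-fold higher with both were 166 genes, among them FOXJ1, CDC20B and CRISP3, and at least 2-fold lower with both were 190, among them GINS2, MYBL2 and ANLN. Unchanged libraries sharing 1 control gave a mean of 42.4 and 42.8 genes in simulation, and independent lists would share 5.99 and 7.30. The log2 changes correlated at r = 0.742 across genes (0.498 simulated), with a covariance of 0.290 (0.104 simulated), and 85.03% had the same sign (66.1% simulated). For protein-coding genes alone, chosen after seeing the data, r was 0.903 (0.498 simulated), the covariance 0.158 (0.0205 simulated), and 74 and 146 genes were 2-fold higher and lower with both, against 2.13 and 2.03 simulated and 1.24 and 4.85 for independent lists. The simulations let the control vary only as the shRNA libraries do. Part or all of the excess may therefore come from the shared control, which is 1 library and cannot be split. The deposited intervals of both shRNAs lay above that of the control in 11 genes and below it in 29.

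**Figure D3:**
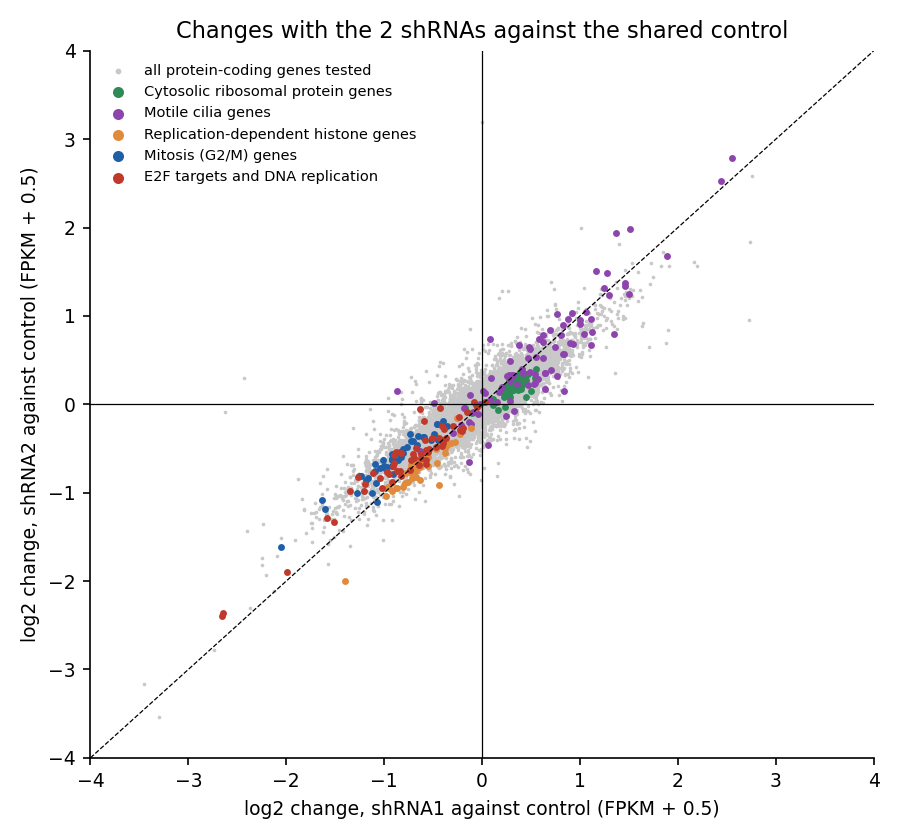
Log2 change with shRNA2 against log2 change with shRNA1, both on the log2(FPKM + 0.5) scale and against the same control library, with 1 point per tested protein-coding gene and fixed gene lists in colour, besides a motile cilia list written after the values were seen. The changes correlate at r = 0.903 across genes, against 0.498 for simulated unchanged libraries sharing a control, and the dashed line marks equal change.

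The comparison of the shRNAs with each other asks how far their effects differ. At least 2-fold apart were 135 genes, 18 of them protein-coding. The 10 genes furthest apart were all listed at 0 in 1 of the 2 libraries. MIR1244-2 was at 0 with shRNA1 and 686 FPKM with shRNA2, RNY3P1 at 0 and 167, RNU6-1 at 0 and 158, a Y_RNA copy at 0 and 83.5, and SNORD67 at 0 and 74.7. In the other direction MIR1291 was at 337 FPKM with shRNA1 and 0 with shRNA2, RNY4 at 212 and 0, SNORD116-25 and SNORD116-16 at 169 and 0, and the pseudogene RP11-328L11.1 at 149 and 0. No gene had deposited shRNA intervals that lay apart (0 of 13108). Across protein-coding genes the slope of the shRNA2 change on the shRNA1 change was 0.739. The median log2 change with shRNA1 and shRNA2 was -0.92 and -0.63 for mitosis genes and -0.48 and -0.24 for interferon-stimulated genes. Histone genes went slightly the other way, at -0.67 and -0.73. Each shRNA has 1 library, so these differences have no replicate check.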

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

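Chosen only after the data were seen were the tests on protein-coding genes alone, on genes above 0 in all libraries, on genes with status OK and with the GC and length trend removed. Pseudocounts, median-ratio scaling, a mean FPKM of at least 5 and status OK kept the numbers of limma calls within 1.5 times 11 higher and 35 lower. Higher and lower calls numbered 0 and 0 with no filter (5039 genes at an unadjusted p under 0.05 in limma), 65 and 111 with the same total, 430 and 595 with robust eBayes, 821 and 1299 for protein-coding genes, 699 and 953 for genes above 0 and 372 and 478 with the trend removed. Without the eBayes trend 6 were higher. Protein-coding genes make up 12 of the 46 calls, and those 12 were all called when tested alone. Genes 2-fold higher with both shRNAs numbered 107 with a pseudocount of 1, 63 at a mean FPKM of at least 5, 74 for protein-coding genes, 574 at 1.5-fold and 235 to 334 with a single shRNA. Genes 2-fold lower numbered 110, 786 and 223 to 429 at a mean of at least 5, at 1.5-fold and with a single shRNA. A filter, a gene type or a fold bound changes such counts by construction. The correlation was 0.903 for protein-coding genes and 0.874 for genes above 0. The covariance, 0.290 in the main fit, was 0.437 with a pseudocount of 0.1, 0.183 with no filter, 0.158 for protein-coding genes and 0.175 for genes above 0. Genes 2-fold apart between shRNAs numbered 298 with no filter, 64 at a mean of at least 5, 18 for protein-coding genes and 61 above 0. Of the lists, 0 passed camera with an estimated correlation (0 at an unadjusted p under 0.05) and 0 passed fry (1 at an unadjusted p under 0.05). Fry asks whether a list moves one way on balance, not whether it differs from other genes. Both draw on the 1 residual degree of freedom, so a list that fails them is not thereby shown to be unchanged. The gene ESR1 turned to -0.039 with the same total. Otherwise the cause was not tested. Named genes kept direction and call in 943 comparisons with an alternative, gained a call in 264, lost it in 9 and reversed in 1. Lists kept it in 284, lost it in 36 and gained it in 1, the luminal list with the trend removed. Leaving out an shRNA in limma leaves no residual degrees of freedom, so it gives values with no test. No paired analysis was possible because the control is 1 library and the samples hold no pairs. Depth was estimated and not varied, so what it limits was not tested.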

Other observations

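Tests on GC and length, on the 3' UTR word and on other choices of the lone library were chosen only after the results were seen, as was the list of motile cilia genes. Genes of motile cilia were higher with both shRNAs. Of 88 measured, 70 were higher and 11 lower with both, with a median log2 change of 0.49. FOXJ1 and CDC20B passed limma over all genes. CCNO, a regulator of centriole amplification, was at 7.89, 15.3 and 16.7 FPKM in control, shRNA1 and shRNA2, its partner in that programme MCIDAS at 2.27, 3.35 and 3.86, the ciliary protein CFAP126 at 0.481, 2.29 and 3.38, the dynein assembly factor DNAAF1 at 0.697, 2.34 and 2.47, and the transcription factor MYB, which the estrogen list also holds, at 4.31, 10.003 and 7.98. These 5 genes were chosen after their values were seen, and none passed limma over all genes. A hypothesis is that a wider motile cilia programme may be raised. Without the genes at least 2-fold higher with both shRNAs, the other 75 had a median of 0.41, at the 100th percentile of matched random lists with each shRNA. The 2 percentiles are not independent, since both use the same control, and they take no account of correlation between members. Camera, run on these 75 genes after the values were seen, gave an unadjusted p of 1.83e-07 at the preset correlation and of 0.177 at an estimated correlation of 0.039. With an estimated correlation camera works with the 1 residual degree of freedom, so the second value does not decide the question. The comparison rests on 1 control library, so it does not separate ERINA from a state of that library.

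Genes around ERINA showed no excess of change as a set. A local effect of ERINA on its neighbours could raise the size of change there. The 11 measured protein-coding genes within 2000000 bases had a median absolute log2 change of 0.12, at the 8.16th percentile of matched sets. None lay close to ERINA, which spans 117415509 to 117546298. The nearest were SEMA6A, ending at 116574934, and DTWD2, starting at 118837322. An effect on closer genes, or on a few of the 11, was therefore not tested. The largest was TMED7-TICAM2, at 1.71, 1.05 and 1.19 FPKM, a read-through gene that overlaps TMED7.

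E2F targets and mitosis genes were lower with both shRNAs. A trend on GC content or transcript length is argued against as the whole cause, since the E2F median was -0.63 with that trend removed. Direct action of a 3' UTR word on the lists' own transcripts is argued against as the whole cause, since the 78 members with neither GGTGCA nor TGGTGC had a median of -0.67, but a part stays open, since the 7 E2F members holding TGGTGCA had a median of -1.09 against -0.58 for the 41 with neither site. A state of the control culture unrelated to ERINA cannot be told apart from an effect of the knockdown, because 1 control library serves both shRNAs. Fewer cycling cells after loss of ERINA may be a biological explanation, which stays open and untested.

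The word TGGTGCA in the 3' UTR had the lowest z of 15847 words tested (-12.51 with shRNA1 and -12.29 with shRNA2), found by an exploratory search, and in the difference of shRNA1 from shRNA2 it ranked 2 from the lowest, at -6.27, after ATGGTGC at -6.62. Of 1503 genes with the word 853 were lower with both shRNAs (median log2 change -0.14), against 4274 of 9941 without it (median -0.0001), and 35.7% of 140 genes 2-fold lower with both held it, against 13.1% of all and 8.1% of 74 higher genes. The lowest z was at least 3.14 times the highest in size. Chance is argued against, as far as genes vary independently, since changes shuffled over genes reached only -4.38. Shuffling breaks any link between change and 3' UTR composition, so it cannot decide on composition. Length and GC content of the 3' UTR were removed before scoring, and other features of composition stay open. ERINA's 617-nt transcript holds the word 1 time, at nucleotide 167, in exon 1, at 117455429 to 117455435 on chromosome 5 of GRCh38, and 6.54% of all 7-base words occur in ERINA transcripts. A decoy for an endogenous small RNA with this seed needs that site, as does a hairpin strand made to match ERINA, where both hairpins would have to share the 1 site, while other hairpin products need none, so at position 167 these cannot be told apart without the hairpin sequences.

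Short RNA genes were far apart between libraries. Genes listed at 0 in 1 library and at 10 FPKM or more in the other numbered 31 between the shRNA libraries and 48 and 40 between control and each shRNA, a ratio of 0.705, which is consistent with few fragments on short genes as a source. By the bounds used to estimate depth, some of those values stand for a single fragment. In the control VTRNA1-3, at 373 FPKM with an upper bound of 1118, and RNU6-2, at 51.0 with 153, are of this kind. Others, such as SNORD116-14 at 248 with 8177, have wider bounds, and how many fragments they stand for is not known. Taking each library in turn as the lone one gives 3 splits, too few for a share under 0.05; the real one gave 46 calls, the highest other 15, and 1 of the 3 reached the real value. In each other split the difference between knockdown and control falls into the error term, so few calls there follow from the design and say nothing about chance.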
